A study of Danio rerio with 11 samples.

How the data were processed

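Whole zebrafish embryos of the TG(fli1:EGFP) line, which carries a green reporter in blood vessels, were profiled by RNA sequencing at 48 hours after fertilisation. The 11 libraries are 5 wild-type (WT) samples and 6 samples from aldh3a1 knockouts (aldh3a1_KO), each given as a replicate in the labels. The labels do not say whether replicates were separate clutches or pools, so the p-values measure only the spread between these 11 samples. Per the labels, embryos were kept in E3 medium with or without PTU, a compound that suppresses pigment, and which samples received it is not given. Libraries were made for the BGISEQ-500 sequencer.

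The authors trimmed reads with Trim Galore 0.6.4 and quantified them with kallisto, whose version the labels give as 0.4.6, and named the build danRer11. The deposited files hold expected counts per gene, which are kallisto's estimated counts and not whole numbers. A second deposited file per library holds TPM per gene, transcript abundance already scaled by the authors for length and depth. Both list 30243 Entrez gene identifiers, of which 25812 matched a symbol in a RefSeq gene table. That table is on the assembly GRCz12tu, not on danRer11, so it gave names and the order of genes but no coordinates. The estimated counts were rounded to whole numbers for the tests.

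Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were filtered with filterByExpr, libraries were scaled by TMM, and genotype was tested with the robust quasi-likelihood F test, two-sided. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all 22182 genes tested. Log2 fold changes are aldh3a1_KO against WT with a standard error (SE) taken from the F statistic. Levels are TMM-scaled CPM as mean and SD over 5 WT and 6 aldh3a1_KO libraries. The TMM scaling leaves the median gene at a log2 fold change of -0.12, and log2(TPM + 1) leaves it at -0.33. Directions are signs against 0 on each scale and were not centred on those medians. For genes at 0 in every library of a group, the fold was computed against a floor of 3 counts over the group and is a lower bound. For 1 to 3 counts a 95% interval of the ratio is given. Intervals and floors cover counting error only.

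Before the data were examined, the test, the alternatives, 38 gene lists and the rule for named genes were fixed. The rule takes aldh3a1, and the 10 rising and 10 falling genes with the largest change among those past the threshold with a mean of at least 2 CPM, groups that do not overlap and a given name. It adds up to 4 members of each list with the smallest adjusted p. It always includes the insulin, glucagon, somatostatin, pdx1, gck, pck1, g6pc, insulin receptor, gapdh, vegfaa, kdrl and fli1 genes. Lists were tested against all other genes with camera at a preset correlation of 0.01, with adjustment over the 38 lists, and aldh3a1 was left out of them. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were run beside it. A camera p given with an estimated correlation is unadjusted unless it is called adjusted. Many lens, globin, a2m and pimr genes are near-identical copies that share reads, so the split of counts between copies is uncertain.

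Library measures were compared with exact two-sided permutation tests over all 462 splits of the libraries, adjusted over 5 measures. Correlations within the 6 aldh3a1_KO libraries used exact permutations. Genes near aldh3a1 were compared with all others by Fisher's exact test, two-sided. Whether genes lie close together in gene order was tested with 100000 random draws. The full test was repeated for 60 splits of the 11 libraries into 5 and 6, the real one included. A single library was called far from its group by Dixon's ratio, on log2(CPM + 0.5) for genes. That scale was chosen after counts on both scales were seen.

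Alternatives were DESeq2 1.42.0 size factors and its Wald test, upper-quartile factors, no filter, a filter of 1 CPM in 5 samples, limma voom with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), 1 surrogate variable from sva 3.50.0, the replicate number as a block, and leaving out each library. Added after seeing the data were the analysis without aldh3a1_KO 1, 5 and 6, thinning to the smallest library, leaving out mitochondrially encoded genes, and removing a trend on gene length. The fit with the block also left out aldh3a1_KO 6, whose number no WT library shares in the labels. The workflow was tested on simulated data with these group sizes. Among 20938 simulated genes it recovered 34 of 99 changed 2-fold and 84 of 100 changed 4-fold, with 2 false calls. Library tests and plots used Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Library totals ranged from 9.22 to 19.97 M estimated counts (M, mega).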

Results

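Whole embryos at 48 hours after fertilisation gave 5 WT and 6 aldh3a1_KO libraries. The WT totals were 19.4, 19.9, 19.97, 18.1 and 19.5 M estimated counts (M, mega). The aldh3a1_KO totals were 13.04, 17.2, 11.5, 14.1, 9.22 and 12.9 M. The groups did not overlap, with means of 19.4 ± 0.753 and 12.98 ± 2.65 M (SD, n = 5 and 6, exact permutation p = 0.00433, adjusted p = 0.0216). Transcripts of the 13 mitochondrially encoded genes took 5.02% ± 0.379 of counts in WT and 15.2% ± 8.26 in aldh3a1_KO (SD, n = 5 and 6, exact permutation p = 0.0216, adjusted p = 0.0361). In the order of the replicates, the aldh3a1_KO shares were 25.9, 7.44, 12.1, 5.01, 19.8 and 20.9%, so the ranges overlap. Identifiers without a match in the gene table took 1.71% ± 0.220 and 3.09% ± 0.735 of counts (SD, n = 5 and 6, exact permutation p = 0.0108, adjusted p = 0.0271). The share taken by the 10 most abundant genes was 8.61% ± 1.16 and 15.7% ± 7.18 (SD, n = 5 and 6, exact permutation p = 0.0758, adjusted p = 0.0947). Genes without a count made up 13.03% ± 0.559 and 14.3% ± 1.80 (SD, n = 5 and 6), with an exact permutation p of 0.115.

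The first principal component held 66.1% of the variance and separated the groups. The mean correlation of a library with the WT libraries was 0.964 ± 0.00716 in WT and 0.797 ± 0.0599 in aldh3a1_KO (SD, n = 5 and 6). Within the 6 aldh3a1_KO libraries, that correlation was lower where the mitochondrial share was higher (Pearson r = -0.878, exact permutation p = 0.0278, adjusted over 2 relations p = 0.0444; Spearman rho = -0.771, p = 0.103). Without the 2 libraries farthest from the median share, r was -0.900. Against the library total, r was 0.825 (exact permutation p = 0.0444, adjusted p = 0.0444; rho = 0.771, p = 0.103) and 0.218 without the 2 farthest, so that relation rests on those libraries. No sequencing batch is named in the labels.

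**Figure D1:**
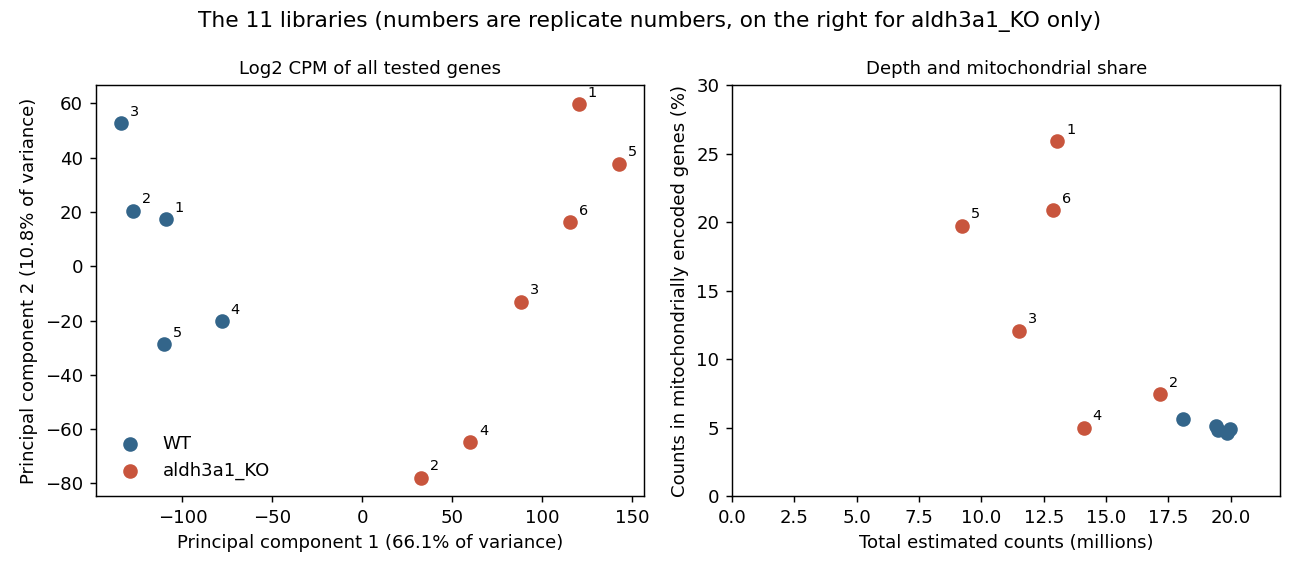
Each point is 1 library, 5 of WT in blue and 6 of aldh3a1_KO in red. Left, the first principal components of log2 CPM, with 66.1% and 10.8% of the variance; right, the share of counts in mitochondrially encoded genes in percent against total estimated counts in M, where all 6 aldh3a1_KO totals lie below the lowest WT total of 18.1 M.

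The comparison of aldh3a1_KO with WT asks what the embryo's transcriptome looks like without aldh3a1, which encodes an aldehyde dehydrogenase that oxidises reactive aldehydes. The transcript of aldh3a1 itself (Entrez gene 100000026) was at 5.79 ± 1.298 CPM in WT and 3.77 ± 1.201 CPM in aldh3a1_KO, a log2 fold change of -0.62 ± 0.27 (SE, n = 5 and 6, edgeR adjusted p = 0.0621). Its TPM was 1.34, 1.35, 1.18, 1.42 and 1.96 in the WT libraries and 0.834, 0.642, 1.297, 1.07, 0.854 and 0.342 in aldh3a1_KO, with overlapping ranges (exact permutation p = 0.00866). On log2(TPM + 1) the log2 fold change was -0.43 with an adjusted p of 0.0457, on a scale where the median of all tested genes was -0.33. Over all alternatives the adjusted p ran from 0.0346 to 0.250. A transcript was thus detected in every aldh3a1_KO library, and the sequence of the mutation was not analysed here.

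Lens, pigment cell, skin and muscle genes were lower in aldh3a1_KO embryos, while mitochondrially encoded transcripts and many photoreceptor and exocrine pancreas genes were higher. As lists these passed camera at its preset correlation, but with an estimated correlation the adjusted p was 0.460 for lens, skin and exocrine pancreas, 0.546 for skeletal muscle and photoreceptors, 0.543 for mitochondrially encoded genes and 0.0556 to 0.460 for the pigment cells. The lens crystallin gene crybb1l1 fell from 439 ± 193 to 7.05 ± 3.11 CPM (log2 fold change -5.95 ± 0.46, edgeR adjusted p = 3.85e-06, n = 5 and 6). The melanosome matrix gene pmela fell from 254 ± 24.4 CPM (log2 fold change -2.21 ± 0.19, edgeR adjusted p = 6.55e-06). The neuronal RNA-binding gene elavl3 rose from 1558 ± 126 to 6272 CPM (log2 fold change 2.01 ± 0.21, edgeR adjusted p = 1.52e-05). Of 22182 genes tested, 12269 changed, 5761 up and 6508 down, which is 55.3%. At least 2-fold changes numbered 4265 up and 4242 down. Groups did not overlap for 8374 genes, or 37.8%, where chance gives 0.433%. Without aldh3a1_KO 1, 5 and 6, the libraries with the highest mitochondrial shares, 11322 genes changed, and 9867 of them also changed, in the same direction, with all 11 libraries. The share of changed genes that were higher was 47.0% with TMM, 33.3% on log2(TPM + 1), 51.99% with DESeq2 size factors, 53.6% with upper-quartile factors and 54.02% with the DESeq2 Wald test, so which direction held more genes depended on the scaling. It was also above 50% without a filter (52.9%), with the length trend removed (51.1%), with the replicate block (50.4%) and without aldh3a1_KO 1, 2, 5 or 6 (52.5, 50.996, 52.4 and 52.5%).

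The largest changes were in single genes that were close to absent from 1 group. The zinc finger gene zfx had 0 counts over the WT libraries and 2460 in aldh3a1_KO, at least 1109.5-fold higher. Of the other rising genes, alg13, a gene of N-glycosylation, had 5 and 256 counts, and the cardiac transcription factor gene nkx2.5 went from 1.98 ± 1.84 to 84.98 CPM (log2 fold change 5.42 ± 0.71). The cytokine genes csf3b (5.32 ± 0.77) and il12ba (4.96 ± 0.67), the trace amine receptor gene taar16g (5.22 ± 0.59), the water channel gene aqp1a.2 (5.09 ± 0.64), the receptor gene f2rl2 (4.96 ± 0.61) and the protease inhibitor genes a2m3h (5.11 ± 0.54) and a2m3g (4.94 ± 0.69) also rose. In the other direction, usf1l, stxbp1b and vamp5 had 1235, 708 and 679 counts in WT and 0 in aldh3a1_KO, at least 304-, 174- and 167-fold lower. WT 5 held 659, 575 and 331 of those counts, and without it the bounds were 179-, 41.3- and 108-fold. The condensin gene ncaph had 2782 and 2 counts, a ratio of 1028 (95% interval 284 to 8493; 1745 and 1762 without aldh3a1_KO 1 or 6), and vamp8, a membrane fusion gene, had 642 and 1, a ratio of 474 (84.9 to 18769), or at least 140.5 without aldh3a1_KO 5, which holds that count. The Notch ligand gene dlc (-8.18 ± 0.65), the lens gene crygm2d1 (-7.43 ± 1.19), trafd1 (-6.71 ± 0.78) and clstn3 (-5.60 ± 0.61) also fell. Without WT 5 the log2 fold change was -4.95 for crygm2d1 and -5.79 for trafd1, and without WT 4 it was 6.09 for nkx2.5 and 6.06 for taar16g.

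**Figure D2:**
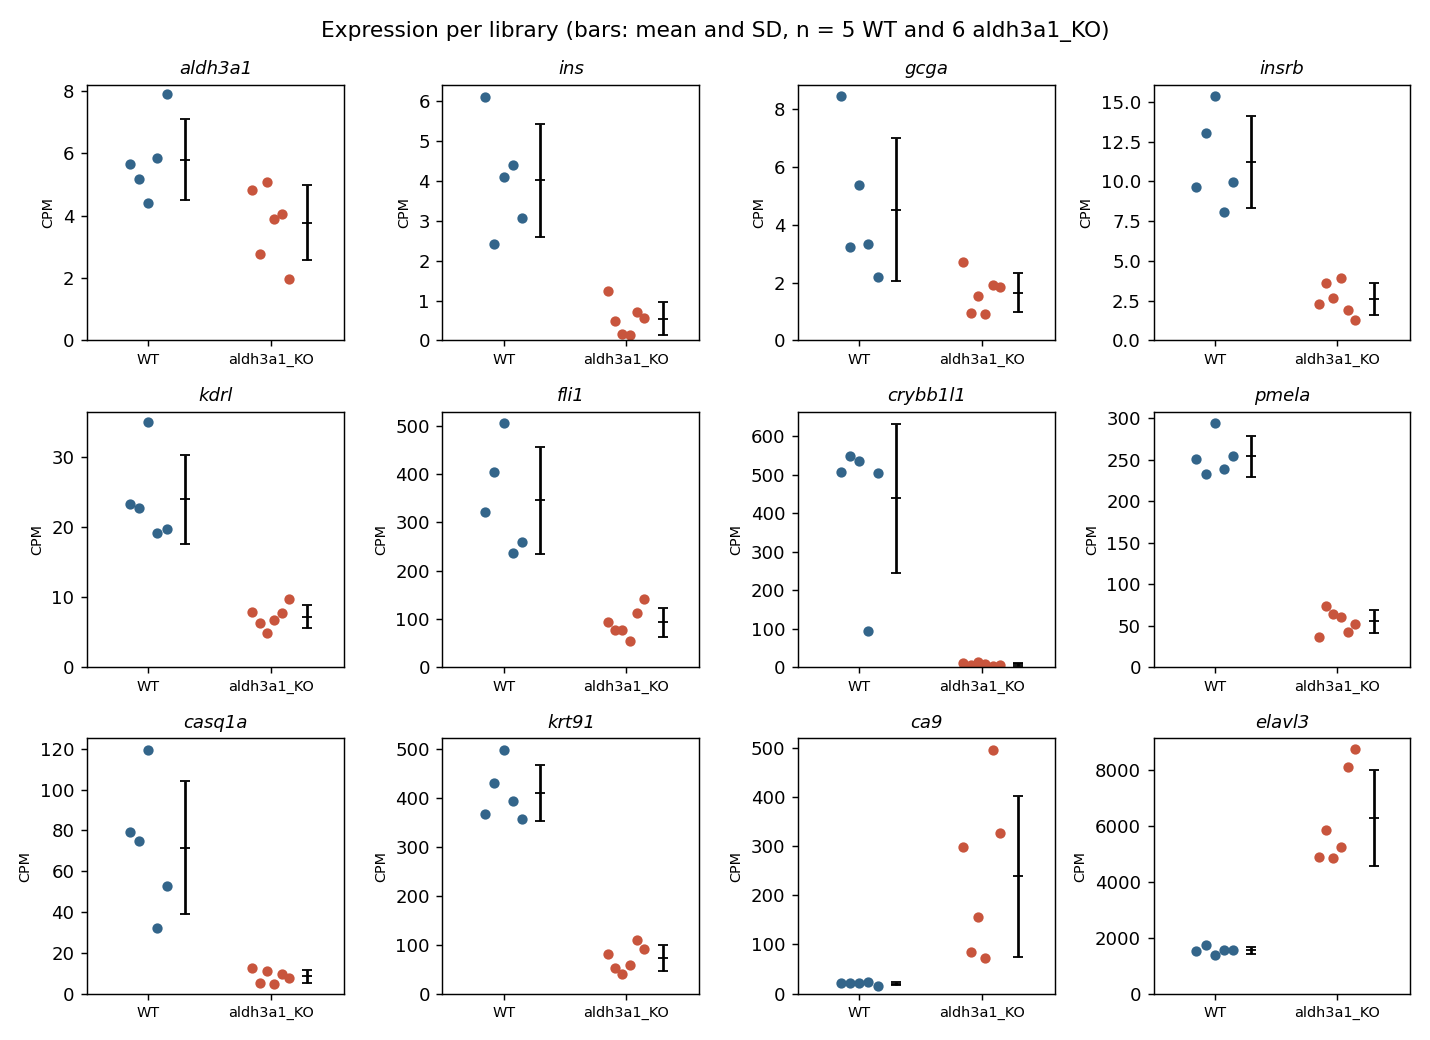
CPM on linear axes from 0 for 12 genes, each point 1 library of 5 WT and 6 aldh3a1_KO, with black bars for mean and SD. The mean of crybb1l1 was 439 CPM in WT and 7.05 CPM in aldh3a1_KO, and that of elavl3 was 1558 and 6272 CPM.

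The insulin gene ins fell from 4.01 ± 1.41 to 0.545 ± 0.406 CPM (log2 fold change -2.91 ± 0.47, n = 5 and 6, edgeR adjusted p = 0.000186) and the glucagon gene gcga by 1.47 ± 0.39 on the log2 scale (adjusted p = 0.00566). The somatostatin gene sst1.1 had a log2 fold change of 0.62 ± 0.32 (adjusted p = 0.11), and without aldh3a1_KO 1 it was 0.91 with an adjusted p of 0.0103. It also passed with voom quality weights (adjusted p = 0.0294), a surrogate variable (0.0239), the replicate block (0.0475) and without aldh3a1_KO 1, 5 and 6 (0.0134). The insulin receptor gene insrb fell by 2.08 ± 0.29, whereas insra was at -0.11 ± 0.13 (adjusted p = 0.51) and turned to 0.01 with upper-quartile factors and 0.04 without aldh3a1_KO 5. The glucose-6-phosphatase genes g6pc1a.2 (1.04 ± 0.26), g6pc3 (0.91 ± 0.22) and g6pc1a.1 (1.35 ± 0.47) rose. For g6pc1a.1 the adjusted p was 0.0652 and 0.0645 without WT 1 or WT 2, 0.247 without aldh3a1_KO 1, 5 and 6, 0.0704 with a surrogate variable and 0.12 on log2(TPM + 1) without a filter. The gluconeogenic gene pck1 was at -0.45 ± 0.75 (adjusted p = 0.624), and 0.20 without WT 3. Too few counts for a test were found for insb (23 in WT and 35 in aldh3a1_KO), pdx1 (42 and 0), gck (55 and 28) and g6pc1b (46 and 37). Of 24 endocrine pancreas genes, 4 rose and 7 fell, and the same adjusted over the list alone (median log2 fold change -0.10, camera adjusted p = 0.428). The median was 0.04, 0.05 and 0.12 without aldh3a1_KO 1, 5 or 6. The hormone-processing genes pcsk2 (-3.17) and scg2a (-2.81) fell, and ghrl, the ghrelin gene, had 2 and 125 counts, a ratio of 84.6 (22.9 to 706), and of 135 and 134 without WT 3 or WT 5.

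Of 12 exocrine pancreas genes, 7 rose and 0 fell, also adjusted over the list alone (median 1.19, camera adjusted p = 0.0261, p = 0.156 with an estimated correlation). The lipase gene cel.1 (5.09 ± 0.76, and 5.87 without WT 5) and the elastase genes ela2l (3.18 ± 0.63) and cela1.4 rose. The call was lost without aldh3a1_KO 1, 2, 4, 5 or 6 (adjusted p = 0.0649, 0.0568, 0.0526, 0.0557 and 0.0614) and without 1, 5 and 6 together (0.118). It was also lost with all libraries thinned to the smallest (0.0503) and with the replicate block (0.0756), which left out aldh3a1_KO 6 as well. Of 31 glycolysis genes, 3 rose and 15 fell, also adjusted over the list alone (median -0.73, camera adjusted p = 0.0346, p = 0.158 with an estimated correlation). In it hk1 was at -3.02 ± 0.49, ldhba at -1.05 ± 0.16 and gapdh at -1.54 ± 0.39. Without aldh3a1_KO 2, 4 or 5 its adjusted p was 0.0657, 0.0526 and 0.0508. It was 0.0532 thinned and 0.0796 with the length trend removed. Of 26 genes of gluconeogenesis and glycogen, 7 rose and 11 fell, also adjusted over the list alone (median -0.42, camera adjusted p = 0.377), among them slc37a4b (-1.82), fbp1a (-1.61) and gbe1a (3.48). Of 34 insulin and IGF signalling genes, 4 rose and 13 fell, also adjusted over the list alone (median -0.37, camera adjusted p = 0.0533). In it igfbp2a (-1.91), akt1 (-2.24) and igf2b (-1.38) fell. With an estimated correlation the list's adjusted p was 0.460, and its median ran from -0.546 to -0.223 when 1 library was left out. That list passed without WT 1, WT 4 or aldh3a1_KO 1, 3 or 5 (adjusted p = 0.0427, 0.0474, 0.0447, 0.0432 and 0.0438), without aldh3a1_KO 1, 5 and 6 (0.049), at 1 CPM (0.0468) and with the length trend removed (0.0344).

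Of 19 other aldehyde dehydrogenase genes, 13 fell and 0 rose, also adjusted over the list alone (median -0.94, camera adjusted p = 0.00103, p = 0.0832 with an estimated correlation), including aldh6a1 (-1.41 ± 0.18), aldh2.2 (-1.80 ± 0.25), aldh4a1 (-2.48 ± 0.35) and the retinoic acid enzyme aldh1a2 (-1.09 ± 0.19). Of 32 genes of carbonyl and conjugating detoxification, 22 fell and 3 rose, also adjusted over the list alone (median -0.97, camera adjusted p = 0.000307, p = 0.0686 with an estimated correlation), with the glutathione transferase gene gstp1.2 going from 213 ± 14.5 to 64.9 ± 18.6 CPM. Of 36 oxidative stress genes, 22 fell and 2 rose, also adjusted over the list alone (median -0.75, camera adjusted p = 0.00339, p = 0.0531 with an estimated correlation), with sqstm1 at -1.52 and prdx6 at -0.85. Of 50 genes of heat shock and the unfolded protein response, 21 fell and 4 rose, or 20 and 4 adjusted over the list alone (median -0.50, camera adjusted p = 0.0188, p = 0.28 with an estimated correlation), including the collagen chaperone gene serpinh1a (-2.20). With an estimated correlation the camera adjusted p was 0.460 for aldehyde dehydrogenases, detoxification and oxidative stress, and 0.543 for heat shock.

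The VEGF receptor gene kdrl fell from 23.9 ± 6.38 to 7.19 ± 1.64 CPM and the endothelial transcription factor gene fli1 from 346 to 92.5 CPM, while vegfaa was at 0.25 ± 0.16 (adjusted p = 0.191) and -0.19 on log2(TPM + 1). Of 40 endothelial genes, 20 fell and 7 rose, also adjusted over the list alone (median -0.70, camera adjusted p = 0.0113, p = 0.108 with an estimated correlation), with the apelin gene apln at -1.57, its receptor gene aplnra at -2.20 and mrc1a at -2.09. Of 35 erythroid genes, 18 fell and 7 rose, or 21 and 7 adjusted over the list alone (median -0.69, camera adjusted p = 0.108, and 0.0427 without WT 1), and klf1, an erythroid transcription factor gene, was at 2.12. Of 30 hypoxia response genes, 13 fell and 5 rose, also adjusted over the list alone (median -0.30, camera adjusted p = 0.336). In it, ca9, a carbonic anhydrase gene, rose from 20.6 ± 2.91 to 238 CPM and egln3, an oxygen-sensing hydroxylase gene, from 9.84 ± 4.60 to 124 CPM, while bnip3la fell by 2.94.

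In the eye, 42 of 47 lens genes fell and 2 rose, or 43 and 2 adjusted over the list alone (median -3.31, camera adjusted p = 5.41e-14, p = 0.101 with an estimated correlation). The crystallin genes cryba2b (-4.78 ± 0.36) and cryba1l1 (-4.26 ± 0.39) stood beside crybb1l1. Of 48 photoreceptor genes, 18 rose and 6 fell, also adjusted over the list alone (median 0.27, camera adjusted p = 0.0291, p = 0.391 with an estimated correlation), with tulp1b at 4.65, the arrestin gene saga going from 21.4 ± 4.87 to 98.7 ± 36.6 CPM, and the rod factor gene nrl at -3.93. Without WT 2 or WT 3 the median was 0.08 and 0.06 and the adjusted p 0.0693 and 0.0923, and with upper-quartile factors the adjusted p was 0.0525. Of 20 genes of the retinal pigment epithelium, 6 fell and 0 rose, or 5 and 0 adjusted over the list alone (median -0.69, camera adjusted p = 0.256), lrata at -2.04 among them. Pigment cell lists stand beside the unknown use of PTU. Of 25 melanophore genes, 18 fell and 2 rose, also adjusted over the list alone (median -1.33, camera adjusted p = 1.14e-05, p = 0.00146 with an estimated correlation, where the adjusted p of 0.0556 no longer passed), among them slc45a2 (-1.93 ± 0.16) and tyrp1a (-2.09 ± 0.19). With an estimated correlation the melanophore list passed with DESeq2 size factors (adjusted p = 0.0389), with upper-quartile factors (0.0171) and without WT 3 (0.0227), and over all alternatives its adjusted p ran from 0.0171 to 0.286. Of 21 xanthophore genes, 15 fell and 2 rose, also adjusted over the list alone (median -1.44, camera adjusted p = 0.00202, p = 0.19 with an estimated correlation), gch2 at -1.85. Of 18 iridophore genes, 15 fell and 2 rose, also adjusted over the list alone (median -1.68, camera adjusted p = 5.81e-05, p = 0.017 with an estimated correlation, where the adjusted p of 0.230 no longer passed), alx4a at -2.43. That adjusted p was 0.0330 without WT 3.

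**Figure D3:**
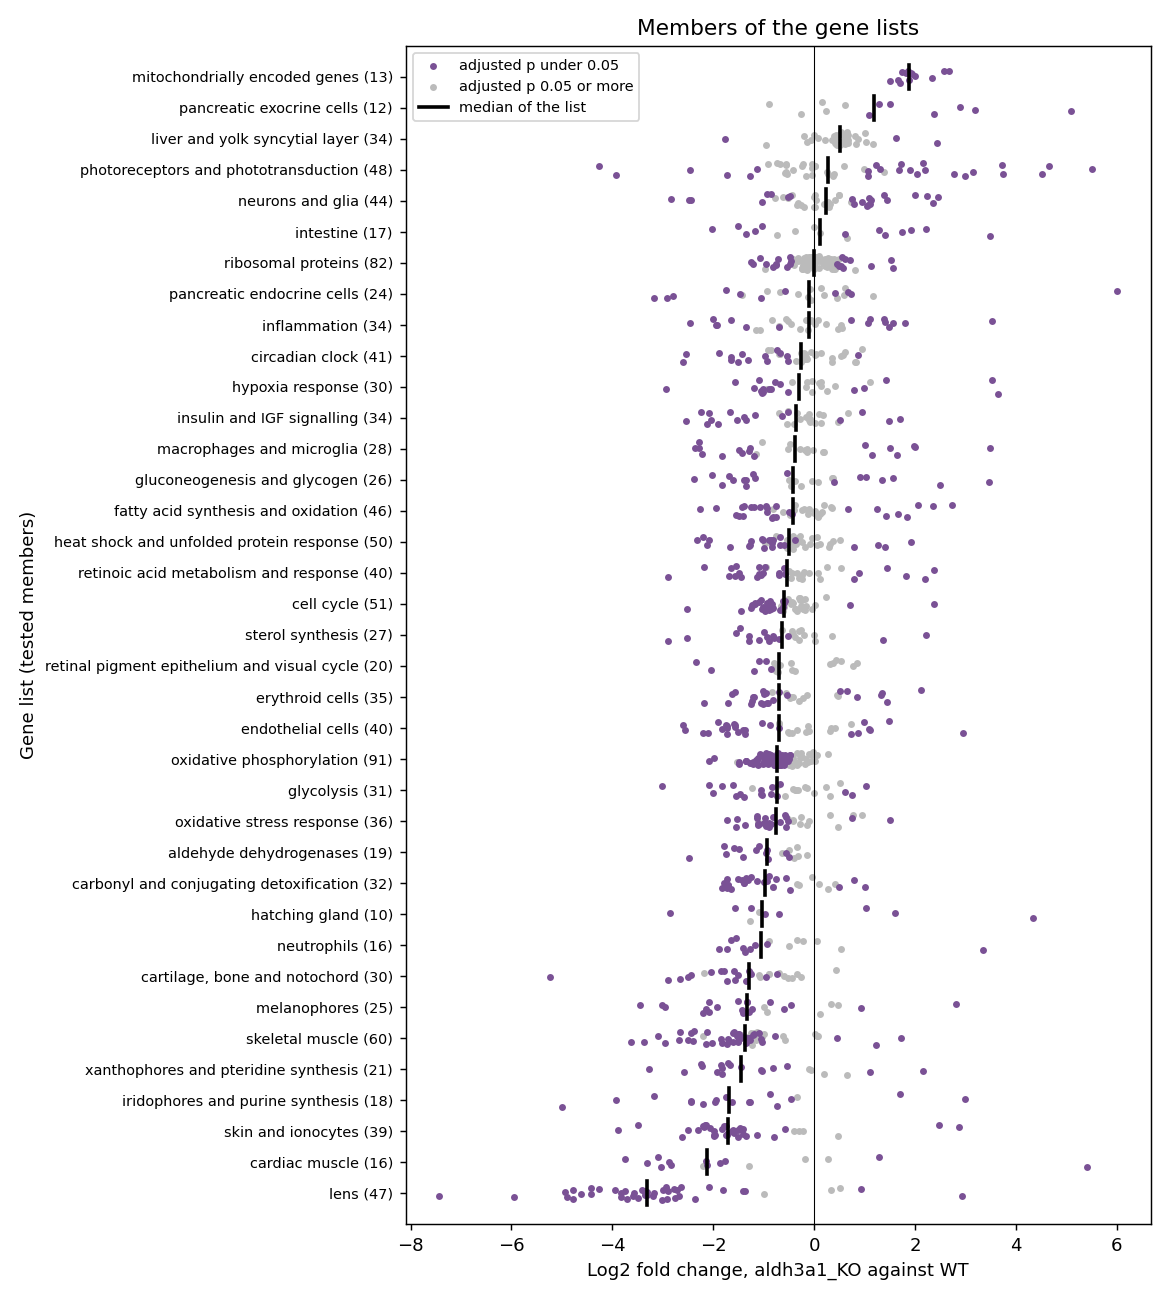
Log2 fold change (aldh3a1_KO against WT) of each tested member of the gene lists described here, 1 point per gene, purple at an adjusted p under 0.05 and grey otherwise, with a black bar for the list's median and the number tested in brackets. Lens genes have the lowest median at -3.31 and mitochondrially encoded genes the highest at 1.89.

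Of 60 skeletal muscle genes, 38 fell and 3 rose, or 44 and 3 adjusted over the list alone (median -1.37, camera adjusted p = 2.69e-05, p = 0.389 with an estimated correlation), with the calcium store gene casq1a at -3.09 and the slow myosin gene smyhc1 at -3.37. Without aldh3a1_KO 2, 25 of the muscle genes fell. Of 16 cardiac genes, 10 fell and 2 rose, also adjusted over the list alone (median -2.13, camera adjusted p = 0.0264, p = 0.323 with an estimated correlation), hand2 at -3.32 and tnnt2a at -2.87, against nkx2.5 above. Its adjusted p was 0.0519 without aldh3a1_KO 2 and 0.0532 thinned. Of 30 genes of cartilage, bone and notochord, 18 fell and 0 rose, or 19 and 0 adjusted over the list alone (median -1.29, camera adjusted p = 7.08e-05, p = 0.179 with an estimated correlation), with the collagen genes col2a1a at -2.51 and col10a1a at -5.23. Of 39 skin and ionocyte genes, 33 fell and 2 rose, also adjusted over the list alone (median -1.71, camera adjusted p = 1.77e-07, p = 0.136 with an estimated correlation), with the keratin genes krt91 at -2.51 and krt5 at -1.96. Of 10 hatching gland genes, 5 fell and 3 rose, also adjusted over the list alone (median -1.04, camera adjusted p = 0.336), the hatching enzyme gene he1.1 at -2.86. Of 44 genes of neurons and glia, 14 rose and 8 fell, also adjusted over the list alone (median 0.23, camera adjusted p = 0.285), with the synaptic vesicle gene vamp2 at 2.35 and the glutamate transporter gene slc17a6a at -2.44. Of 34 genes of liver and the yolk syncytial layer, 2 rose and 1 fell, also adjusted over the list alone (median 0.52, camera adjusted p = 0.147, and 0.0454 without WT 4), plg at 2.44. Its median was -0.31 without aldh3a1_KO 1, 5 and 6. Of 17 intestine genes, 7 rose and 5 fell, also adjusted over the list alone (median 0.13, camera adjusted p = 0.516), tm4sf5 at 3.49. The median was -0.30 without aldh3a1_KO 5 and -0.02 without 6.

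All 13 mitochondrially encoded genes rose, also adjusted over the list alone (median 1.89, camera adjusted p = 0.000447, p = 0.279 with an estimated correlation), ND6 at 2.01 ± 0.32. Without aldh3a1_KO 1, 5 and 6 the number was 9 with a median of 0.83. Of 91 nuclear genes of oxidative phosphorylation, 66 fell and 0 rose, or 69 and 0 adjusted over the list alone (median -0.73, camera adjusted p = 1.77e-07, p = 0.286 with an estimated correlation), ndufa9a at -1.35 and ndufa10 at -1.49. Of 82 ribosomal protein genes, 10 rose and 12 fell, or 5 and 8 adjusted over the list alone (camera adjusted p = 0.644). The number that rose ran from 5 without WT 2 or WT 3 to 21 without aldh3a1_KO 5. Their median was -0.01 and their mean just above 0, and the median was 0.09 with DESeq2 size factors and above 0 without WT 1, WT 4 or any 1 of the aldh3a1_KO libraries, up to 0.13 without aldh3a1_KO 5. Of 51 cell cycle genes, 25 fell and 2 rose, also adjusted over the list alone (median -0.60, camera adjusted p = 0.00456, p = 0.539 with an estimated correlation), the cyclin gene ccnb3 at -2.52. Without aldh3a1_KO 1, 5 and 6 the adjusted p was 0.0689, the median -0.26 and the number that fell 17. The median of the cell cycle genes ran from -0.640 to -0.374 when 1 library was left out. Of 27 sterol genes, 14 fell and 2 rose, also adjusted over the list alone (median -0.64, camera adjusted p = 0.0523), srebf1 at -2.52. The adjusted p was 0.0447 without WT 1, 0.0447 without WT 2, 0.0479 without WT 3, 0.0453 without aldh3a1_KO 3 and 0.0499 with DESeq2 size factors. It was 0.180, with a median of -0.25, without aldh3a1_KO 1, 5 and 6, and 0.460 with an estimated correlation. The median of the sterol genes ran from -0.727 to -0.379 when 1 library was left out. Of 46 fatty acid genes, 19 fell and 8 rose, or 21 and 8 adjusted over the list alone (median -0.42, camera adjusted p = 0.147), lpla at -2.26 and elovl5 at 1.83.

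Of 34 inflammation genes, 9 rose and 7 fell, also adjusted over the list alone (median -0.10, camera adjusted p = 0.908), the antiviral gene mxa at 3.52. The median was 0.00 with DESeq2 size factors, 0.03 without WT 4, 0.05 without aldh3a1_KO 2, 0.01 without 5 and 0.05 without 6. Of 16 neutrophil genes, 9 fell and 1 rose, also adjusted over the list alone (median -1.06, camera adjusted p = 0.0533, and 0.0434 or 0.0223 without aldh3a1_KO 1 or 6), cebp1 at 3.36. That list also passed with a surrogate variable (adjusted p = 0.0323) and without aldh3a1_KO 1, 5 and 6 (0.0166). It passed with the replicate block (0.0336), which also left out aldh3a1_KO 6. With an estimated correlation its adjusted p was 0.545. Of 28 macrophage and microglia genes, 10 fell and 7 rose, also adjusted over the list alone (median -0.37, camera adjusted p = 0.518), lcp1 at -2.36. Of 40 genes of retinoic acid metabolism and response, 18 fell and 6 rose, or 19 and 6 adjusted over the list alone (median -0.53, camera adjusted p = 0.0533), with the degrading enzyme gene cyp26a1 at -1.68 and hoxb4a at -2.90. It passed without WT 1, 4 or 5 or aldh3a1_KO 1 or 3 (adjusted p = 0.0447, 0.0497, 0.0428, 0.0492 and 0.0345) and with the replicate block (0.0276). Without aldh3a1_KO 1, 5 and 6 the adjusted p was 0.0788 (median -0.41), and with an estimated correlation it was 0.517. Of 41 circadian genes, 14 fell and 1 rose, or 13 and 1 adjusted over the list alone (median -0.26, camera adjusted p = 0.0651), bhlhe40 at -1.64. That adjusted p was 0.0427 or 0.037 without WT 1 or aldh3a1_KO 4, and 0.045 with the length trend removed. With an estimated correlation it was 0.545, and the median ran from -0.385 to -0.110 when 1 library was left out.

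By camera, 20 of the 38 lists passed at the preset correlation. The result of 1 of these lists is counted here but not described. With an estimated correlation 0 passed after adjustment in all 11 libraries with TMM, the lowest adjusted p being 0.0556 for melanophores, and 3 had an unadjusted p under 0.05. By fry, which does not compare a list with other genes, 30 passed. With 55.3% of all tested genes changed, many lists can pass fry whatever their members share. Without aldh3a1_KO 1, 5 and 6, 20 lists passed by camera at the preset correlation. Camera compares a list with all other tested genes, and these differed by class. Of coding genes with a given name, 20.2% rose and 33.4% fell (median -0.24). The median was 1.06 for long non-coding genes and 1.01 for identifiers without a match. List members were matched by symbol, so part of a list's fall may be that of its class. Lists were not tested against named coding genes alone.

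Genes next to a mutated locus can differ between lines, so gene order around aldh3a1 in the GRCz12tu table was compared. Of the 100 nearest tested genes, 57 changed, against 55.3% elsewhere (odds ratio 1.07, Fisher's exact p = 0.763). Log2 fold changes of at least 5 in size were found in 2 of the nearest 50 (Fisher's exact p = 0.0348), 2 of 100 (p = 0.117) and 2 of 200 (p = 0.328). Those genes were dlc and timm50, a mitochondrial import gene with 424 counts in WT and 0 in aldh3a1_KO, which was named after its values were seen. Between them and aldh3a1 lie tnfaip1 (-2.51 ± 0.63), sgsm2 (-0.13 ± 0.25) and tpst1 (-1.35 ± 0.29), and aldh3a2a on the far side was at -0.50 ± 0.23.

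**Figure D4:**
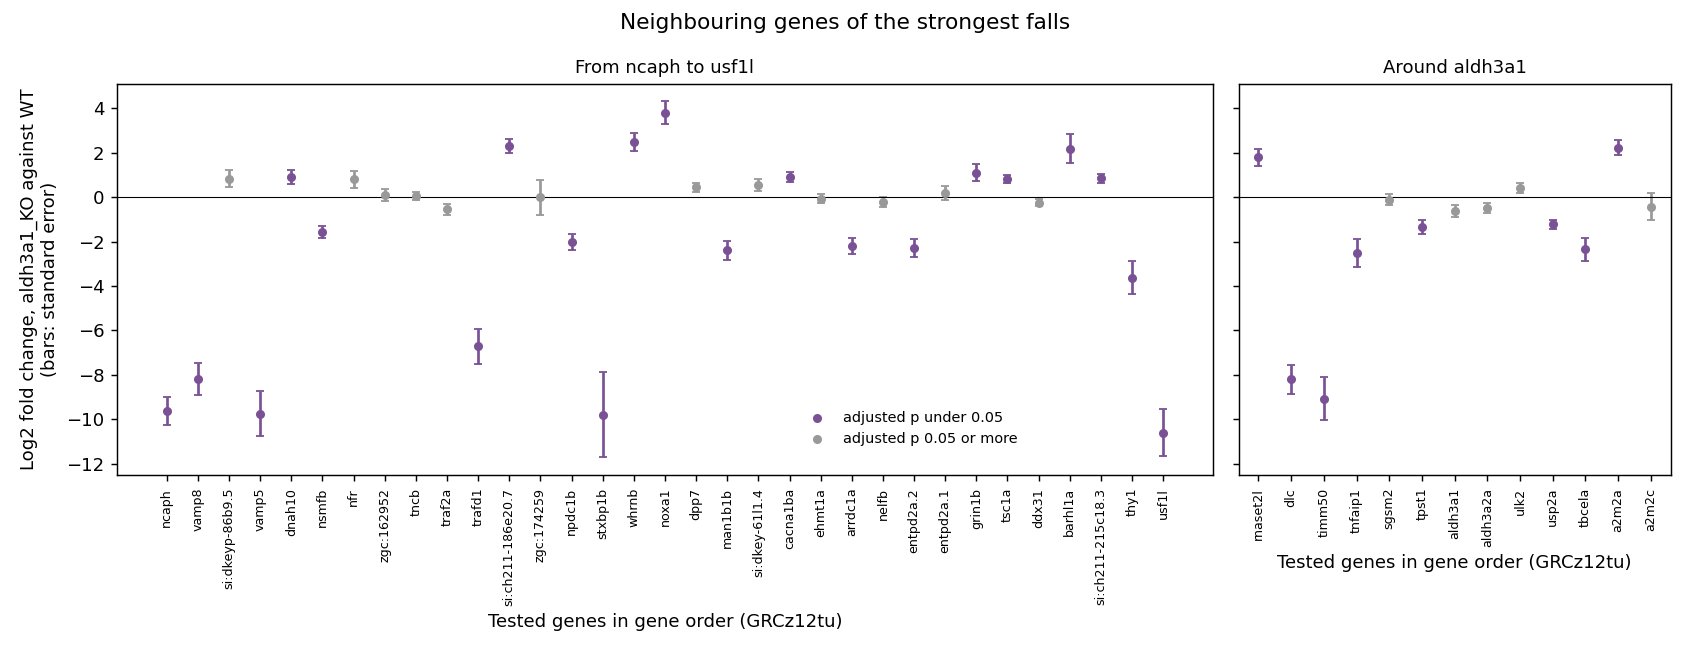
Log2 fold change (aldh3a1_KO against WT) of tested genes in the order of the GRCz12tu table, from ncaph to usf1l on the left and around aldh3a1 on the right, with bars for the SE, purple at an adjusted p under 0.05 and grey otherwise. Points for genes at 0 counts in aldh3a1_KO (usf1l, stxbp1b, vamp5 and timm50) are fitted values that depend on the prior count; ncaph, vamp8, trafd1 and dlc also lie below -5.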

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

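The tests of depth, of the libraries with a high mitochondrial share and of gene length for the number of changed genes, and every test on closeness in gene order, were chosen after the result was seen, and so were the settings that leave out aldh3a1_KO 1, 5 and 6 and thin the libraries.

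Of 22182 genes, 12269 changed, and 8507 of them at least 2-fold. Of 60 splits of the libraries only the real one, 1.67% of them, gave as many for either count, which argues against chance for both. The highest other split, with 9897 and 7054, set 5 aldh3a1_KO libraries against all WT libraries and the remaining aldh3a1_KO library. It is thus close to the real split, and no other gave more than 1 changed gene. For the 20 lists called chance stays open, since 14 of 60 splits, the real one included, gave as many and the highest of the others gave 25. Thinning every library to the smallest left 11182 genes, leaving out aldh3a1_KO 1, 5 and 6, which have the highest mitochondrial shares, 11322, and removing a trend on gene length 12010, which argues against depth, those libraries or length as the whole cause. Leaving out the mitochondrially encoded genes gave 12284 and moved too few calls to test what a high share marks in a library. An effect of the genotype, a difference in stage, strain background or PTU, and a batch the labels do not record may each contribute, and none of these was tested.

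Long non-coding genes and identifiers without a match in the gene table, classes named after the values were seen, had larger shares of risen genes (295 of 532 and 954 of 1790) than coding genes with a clone or locus name (1063 of 2914) or a given name (3406 of 16859), with 43 of 87 for the remaining classes, and the difference itself was not tested. Median WT levels were 1.504 CPM for long non-coding genes, 1.548 for unmatched identifiers, and 3.384 and 13.05 for the coding classes in that order. Over all genes at a WT TPM of 0.05 to 0.2, mean summed TPM was 333 in WT and 1301 in aldh3a1_KO. At 5 to 20 it was 67108 and 64925. Classes were not compared at matched levels, so the rise cannot be assigned to class rather than level. Genes near the filter can also pass it through their higher group. A uniform low background would add about the same TPM to each gene. Over the 2312 risen genes without a given name the 90th percentile of the added TPM was 34.5 times the 10th. Those genes were picked as risen, which can widen that spread whether or not a background is present. The ratio therefore cannot decide on a low background. Over all genes at a WT TPM of 0, mean summed TPM was 364 in aldh3a1_KO. That sum could not be lower than in WT, because the genes were picked by their WT level. The same choice favours a higher aldh3a1_KO sum at other low WT levels. Genes were not grouped by their aldh3a1_KO level, so these sums cannot decide on a low background either. With all libraries thinned to the smallest, 57.1% of the long non-coding genes tested rose, and without aldh3a1_KO 1, 5 and 6 48.3% did, which argues against depth and against those libraries as the whole cause. A change in which cells or stages the embryos hold, or a difference in library preparation, may remain, and neither was tested.

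The genes that fell most lay close together: of the 19 placed genes at a log2 fold change of -5 or below, 8 lay within 50 tested genes of another (permutation p = 0.00312; within 25, p = 0.0002; within 100, p = 0.0280), which argues against chance placement, while for the 54 that rose as much the p values were 0.0252, 0.134 and 0.439 at 25, 50 and 100. Of 33 tested genes from ncaph to usf1l, 6 fell that far, and 19 of the other 27 lay above -1 by more than 2 SE, which argues against a deletion of the whole stretch. A haplotype of this stretch that differs between the groups and changes its genes broadly may be present. Of those 27 genes 15 changed, 55.6% against 54.4% elsewhere (odds ratio 1.047, 95% interval 0.457 to 2.45, Fisher's exact p = 1). This cannot be told apart because the interval is wide. A haplotype that changes few of its genes need not raise that share, so the count cannot decide on it. In WT, replicate 5 was highest for all 6 genes, from 1.72 times the next library for ncaph to 10.3 times for stxbp1b.

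Some single libraries lay far from the rest of their group by Dixon's ratio, the gap to the nearest library over the group's range. Chance marks about 1 in 20 groups, or 18 of the 360 gene groups, and 22 were found on log2(CPM + 0.5), the scale reported here, and 31 on the CPM scale. Among library measures, WT 3 had the highest share of the 10 most abundant genes (0.744) and aldh3a1_KO 6 the most genes without a count (0.678). WT 4 was set apart for a2m3h (0.726), il12ba (0.722), grna.1 (0.724), dlc (0.786) and crybb1l1 (0.952). WT 5 was set apart for crygm2d1 (0.775), trafd1 (0.741) and ca9 (0.787), and WT 3 for cela1.4 (0.792), tulp1b (0.722), slc2a15b (0.776) and cd63 (0.723). WT 2 was set apart for ela2l (0.738) and WT 1 for slc17a6a (0.909). Among aldh3a1_KO libraries, replicate 1 was set apart for zfx (0.637), replicate 2 for birc5b (0.634) and g6pc3 (0.642), replicate 5 for vamp8 (1, its single count), aldh2.2 (0.712), lpla (0.640) and ndufa10 (0.632), and replicate 6 for bmal1b (0.754).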

How the results depend on the processing

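The settings without aldh3a1_KO 1, 5 and 6, thinned, without mitochondrially encoded genes and with the length trend removed were chosen after the data were seen. Over all alternatives the number of changed genes ran from 10309 to 14579, and from 11034 to 12505 when 1 library was left out; the number of lists called ran from 17 to 25. With camera's estimated correlation it was 0 under TMM with all libraries, while melanophores passed with DESeq2 size factors (adjusted p = 0.0389), upper-quartile factors (0.0171) and without WT 3 (0.0227), where iridophores passed too (0.0330). Of 179 named genes followed, 172 kept their side of the threshold and their direction in every alternative that gave a value. Most were picked for a large change or small adjusted p in the main test, so this does not measure how stable calls are. Of all genes called in the main test, 73.3% were also called on log2(TPM + 0.1), which tested fewer genes. That share was 80.4% without aldh3a1_KO 1, 5 and 6, and 99.1% at most, without mitochondrially encoded genes. Among the other named genes, rbp4 did not pass in the main test. It passed with voom quality weights (log2 fold change -1.20, adjusted p = 0.0045), a surrogate variable (0.00835), the block (0.0148) and all fits on TPM. It also passed without aldh3a1_KO 6 (0.0387) and without 1, 5 and 6 (-1.95, 0.00128), where serpinc1 lost its call (0.90, adjusted p = 0.139). Fewer genes were higher on log2(TPM + 1), 3486, and log2(TPM + 0.1), 3454, of which 2046 and 2610 were at least 2-fold higher, and 2116 on log2(TPM + 1) without a filter. The log2 fold change of aldh3a1 passed at -0.43 on log2(TPM + 1) with and without a filter (adjusted p = 0.0457 and 0.0346) and at -0.67 with the length trend removed (0.0428). The sign of insra turned with upper-quartile factors (0.0133; leaving out 1 library -0.144 to 0.0362), that of vegfaa on log2(TPM + 1) (-0.194, with and without a filter) and log2(TPM + 0.1) (-0.214), and that of pck1 when 1 library was left out (-0.932 to 0.199). The median of all tested genes was -0.12 with TMM, -0.027 with DESeq2 size factors and -0.00055 with upper-quartile factors. It was -0.33 on log2(TPM + 1), -0.088 there without a filter, and -0.41 on log2(TPM + 0.1). Signs against 0 thus shift with the scaling, and a turn under another scaling need not be a change relative to other genes. How much of each turn this explains was not tested. Medians of lists near 0 also turned, with the same limit. For inflammation they were 6.8e-05 with DESeq2 size factors, 0.0165 with upper-quartile factors, 0.0917 with the block, 0.0630 with the length trend removed and -0.221 to 0.0494 leaving out 1 library. For intestine they were -0.422 with a surrogate variable, -0.294 with the block, -0.730 without aldh3a1_KO 1, 5 and 6, -0.0801 thinned and -0.298 to 0.717 leaving out 1 library, and for liver -0.307 without 1, 5 and 6. For endocrine cells they were 0.0145 with upper-quartile factors, 0.0919 without 1, 5 and 6 and -0.209 to 0.116 leaving out 1 library. For ribosomal proteins they were 0.0862 with DESeq2 size factors, 0.104 with upper-quartile factors, 0.0246 at 1 CPM, 0.0591 with a surrogate variable, 0.0593 with the block, 0.0424 without 1, 5 and 6, 0.0218 thinned, 0.0071 without mitochondrially encoded genes and -0.100 to 0.129 leaving out 1 library. Replicate numbers are shared between the groups, but only 2 of 5 pairs matched best with their own number. The number of WT 5 in its label differs from that in its file, so its pair and the block are uncertain. With the number as a block, which also left out aldh3a1_KO 6, 11125 genes changed, 50.4% of them up. Without aldh3a1_KO 6 alone, 11248 changed, 52.5% of them up. Of the simulated 2-fold changes 34.3% were recovered. That simulation changed only 99 genes 2-fold and 100 genes 4-fold among 20938, whereas 12269 genes changed in the data. The adjusted p is stricter with so few changed genes, so that share does not give the power of this comparison. Smaller effects may still be missed. The planned position tests in fixed distances and by chromosome were not run, because the gene table is on another assembly.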

Other observations

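The gene families and classes here, and both tests near aldh3a1, were chosen after their values were seen.

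Counts for some gene families follow, none tested for enrichment. Over all genes without a filter on low counts, 13403 of 29177 changed, 52.9% of them up. Without that filter, which would keep mainly the members that are high in 1 group, 24 of 98 odorant receptor genes (or) rose and 6 fell, 15 of 43 trace amine receptor genes (taar) rose and 0 fell, and 29 of 48 olfactory class C receptor genes (olfc) rose and 1 fell. Of 80 pim-related kinase genes (pimr), copies of which share reads, 31 rose and 0 fell without a filter. On log2(TPM + 1) without a filter, 19 of 102 or genes rose and 9 fell, and 8 of 49 taar, 20 of 49 olfc and 27 of 80 pimr genes rose. Of 49 hox genes, which pattern the body axis, 28 fell and 2 rose (median log2 fold change -1.17), or 25 and 2 without a filter, and 9 of 11 embryonic globin genes fell and 0 rose with and without it. Of the tested genes with a mean of at least 2 CPM in WT, 8 were close to absent from aldh3a1_KO, at 3 counts or fewer over the group. They were rap1gapa and adm2a, the adrenomedullin-related gene, beside timm50, usf1l, stxbp1b, vamp5, ncaph and vamp8. Of the tested genes with a mean of at least 2 CPM in aldh3a1_KO, 9 were close to absent from WT by the same rule, and zfx alone has a given name.

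The falls of dlc and timm50 beside aldh3a1 may reflect a deletion that reaches from them to aldh3a1, or a haplotype around it. The log2 fold change of sgsm2, which lies between them, was -0.13 ± 0.25, which argues against such a deletion. For a haplotype, 2 of the 100 nearest genes had a log2 fold change of at least 5 in size (Fisher's exact p = 0.117), against p = 0.0348 for 2 of the nearest 50 and p = 0.328 for 2 of 200, and this cannot be told apart with so few genes.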
